A study of Mus musculus with 6 samples.

How the data were processed

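RNA of LT-HSC sorted from mouse bone marrow was measured in 6 libraries, 2 per genotype, made from small numbers of cells by a SMART-seq protocol on polyadenylated RNA, per the labels' protocols. The markers of the sort are not given in the sources used here. The deposited table holds 1 signal value per gene and library, a normalized CPM from edgeR per the file headers, and lists only genes with a value above 0 in at least 1 sample. Per the submitters' processing notes the tools were CASAVA 1.8, TopHat2 2.1.0, Bowtie2 2.2.4, SAMtools 0.1.18, HTSeq 0.6.1p1 and edgeR 3.20.7 with the mouse build mm9, while the annotation, the strand setting and the handling of reads with several matches are not given in the sources used here. The reference tables at hand follow another build, so they were used only for gene symbols and for which genes neighbour each other on the X chromosome, and no coordinates are printed. Overlapping, antisense and near-identical genes may share reads, and the beta-globin genes, near 1 CPM throughout, were not interpreted for that reason. With SMART-seq amplification and no molecular identifiers, reads are not independent molecules, so the floors given cover counting error only.

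The sums of the columns differ, so the authors' CPM is relative to an effective library size rather than to the reads counted. Of the 107982 values 100% were whole multiples of the smallest value of their column within 0.01 reads, the largest deviation being 2.33e-08. The recovered totals were 27088400 and 19287800 reads in Mx replicates 1 and 2, 15618800 and 33346200 in Flt3ITD and 27599100 and 37038900 in NPMc_Flt3ITD. The pre-ribosomal RNA Rn45s took 25.1% and 15.7% of the reads in Mx, 21.3% and 18.7% in Flt3ITD and 22.8% and 21.7% in NPMc_Flt3ITD. Of 17997 genes between 14026 and 16226 were above 0 in a library. The effective size was 0.985 and 1.10 times the total in Mx, 0.975 and 0.946 times in Flt3ITD and 0.969 and 0.934 times in NPMc_Flt3ITD. No library was a copy of another: Pearson correlations of log2(CPM + 1) across genes were between 0.962 and 0.969 within groups and between 0.927 and 0.955 between groups.

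The design had been written for counts, with edgeR's quasi-likelihood test as the main test and limma as the test for a table without counts, before the data were examined. As the table holds normalized CPM, limma 3.58.1 with an intensity trend was applied to log2(CPM + 1) in R 4.3.3, with all 6 libraries in 1 fit, group as the only term and Benjamini-Hochberg adjusted p under 0.05. Genes needed at least 1 CPM in at least 2 libraries, which kept 12657 and removed 5340. This filter was set after the unit was known and was not part of the written design. The fit had 3 residual degrees of freedom and 8.67 after moderation. The comparisons were Flt3ITD against Mx, NPMc_Flt3ITD against Mx and NPMc_Flt3ITD against Flt3ITD, the last being also the test of the difference between the mutant groups. Replicates are biological per the series design text.

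A set of 32 gene lists (stem cell, progenitor, cell cycle, signalling, metabolic and Hox genes, and markers of other cells that a bone marrow sort could hold) was fixed before the data were examined. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry, which tests whether the genes of a list move, on balance, in 1 direction without comparing them with other genes. With an estimated correlation camera also judges a list on the 3 residual degrees of freedom, so more than the correlation differs. For the quiescence list in Flt3ITD against Mx the estimate was -0.00772, below the preset value. Its unadjusted camera p still went from 3.17e-09 to 0.00663. A call lost with an estimated correlation is therefore not by itself a sign of correlated genes. Named genes were, per comparison, the 10 largest rises and 10 largest falls past the threshold with libraries that do not overlap and at least 5 CPM in the higher group, up to 4 members with the smallest p of each reported list, and Flt3, Npm1, Hoxa9, Hoxa10, Meis1, Mecom, Cdkn1c, Cdk6, Mki67, Socs2 and Tgfb1 throughout. Genes named only to describe the libraries or in the closing observations, such as Xist, Ddx3y, S100a8, Igj, Junb, Dppa5a, Alas2, Slc4a1 and Hprt, were chosen after their values were seen.

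The groups share replicate numbers, so it was checked whether these pair the libraries. The deviations from the group means of same-numbered libraries correlated across genes at 0.259 between Mx and Flt3ITD, 0.316 between Mx and NPMc_Flt3ITD and 0.341 between Flt3ITD and NPMc_Flt3ITD, and the third principal component, with 18.8% of the variance, separated the numbers 1 and 2. This pairing was read from the values before fits with and without the block were compared, as the labels do not say what the numbers share. Values with replicate number as a block stand beside a named gene or list where they changed its call. They also stand beside totals and overlaps of changed genes where they moved these by over 1.5 times. Counts of list members past the test are given without the block only and may be larger with it.

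The alternatives planned were DESeq2 size factors, library totals, no filter, a filter at 10 CPM, DESeq2 1.42.0, edgeR 4.0.16 likelihood ratio and limma voom on recovered reads, the replicate block, only the 4 libraries compared, an added fold change threshold of 1 on the log2 scale, pseudocounts of 0.1 and 5, and leaving out each library. The quasi-likelihood test on recovered reads (265, 106 and 77 genes in the 3 comparisons), the same with the block, fry with the block and the overlap of calls with the block were added after the data were seen. The first of these is the main test that the design had written for counts, and only its use on recovered reads was added later. The fits were tested on simulated negative binomial reads with 200 changed genes. Without a replicate effect, limma recovered 83% of 4-fold and 21% of 2-fold changes among 12367 genes for Flt3ITD against Mx, 85% and 21% among 12358 genes for NPMc_Flt3ITD against Mx and 88% and 28% among 12356 genes for NPMc_Flt3ITD against Flt3ITD, with 12, 11 and 12 false calls among 116, 117 and 128. With a simulated replicate effect of SD 0.5 on the log2 scale the fit without the block called no gene in any of the 3, and the fit with the block recovered 87%, 81% and 84% of the 4-fold changes in the same order, with 8, 12 and 4 false calls among 111, 121 and 109. The simulated spread was estimated without the block, so any replicate effect of the data was already in it. In the data the fit without the block called 576, 148 and 149 genes. This setting therefore cannot decide whether the block is needed.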

Results

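The transcriptomes of long-term haematopoietic stem cells (LT-HSC), the rare bone marrow cells that sustain blood formation, were compared between 3 mouse genotypes with 2 biological replicates each. The reference group, Mx, carried the interferon-inducible MxCre recombinase transgene. Flt3ITD cells carried an internal tandem duplication of the receptor tyrosine kinase gene Flt3, and NPMc_Flt3ITD cells carried this duplication together with NPMc+, a mutant nucleophosmin that accumulates in the cytoplasm. No group with NPMc+ alone was analysed here, so its effect could be read only on the Flt3ITD background. The series title places the question in stem cell dormancy and self-renewal during myeloid leukaemia. The animals were C57BL/6 mice of 8 to 11 weeks. Recovered reads per library ranged from 15618800 (Flt3ITD replicate 1) to 37038900 (NPMc_Flt3ITD replicate 2), and 1 read was worth between 0.0289 and 0.0657 CPM. Values are given below as normalised CPM, mean ± SD with n = 2 libraries per group. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes, with the standard error (SE) from limma.

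The levels of the genes that the genotypes name did not pass the limma test in any comparison. Flt3 was at 43.6 and 38.3 CPM in the Mx libraries, 32.5 and 39.8 CPM in the Flt3ITD libraries and 64.3 and 93.6 CPM in the NPMc_Flt3ITD libraries. Adjusted p for Flt3 was 0.682 for Flt3ITD against Mx, 0.13 for NPMc_Flt3ITD against Mx and 0.0668 for NPMc_Flt3ITD against Flt3ITD. The last 2 became 0.0237 and 0.00728 with replicate number as a block. Npm1, which encodes nucleophosmin, was at 1416 ± 251 CPM in Mx, 2064 ± 384 CPM in Flt3ITD and 1536 ± 220 CPM in NPMc_Flt3ITD, with adjusted p of 0.259, 0.91 and 0.447 in the same order of comparisons. The first of these became 0.0161 with the block. A value per gene does not show which allele was read, so neither level checks a genotype.

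The libraries also differed in sex-linked genes and, within groups, in genes of other cells and of stress. Xist, the RNA that coats the inactive X chromosome, was at 1007 and 1038 CPM in Mx, 37.2 and 547 CPM in Flt3ITD and 259 and 625 CPM in NPMc_Flt3ITD. The Y-linked gene Ddx3y ran the other way, from 20.4 CPM in Mx replicate 1 to 63.6 CPM in Flt3ITD replicate 1. Both Mx libraries lay above all 4 mutant libraries for Xist and below them for Ddx3y, so the mix of male and female animals goes with the group in both comparisons against Mx. The neutrophil gene S100a8 was at 3.74 CPM in Flt3ITD replicate 1 and 269 CPM in Flt3ITD replicate 2. The plasma cell gene Igj was higher in replicate 2 of each group, with 6.26 and 82.3 CPM in Mx, 28.1 and 235 CPM in Flt3ITD and 8.34 and 242 CPM in NPMc_Flt3ITD. The immediate early gene Junb was higher in replicate 1 of each group, with 705 and 136 CPM in Mx, 408 and 135 CPM in Flt3ITD and 711 and 227 CPM in NPMc_Flt3ITD. Dppa5a, a gene of embryonic stem cells, was listed at 0 in all 3 replicate 1 libraries and at 22.1, 26.7 and 25.2 CPM in the replicate 2 libraries of Mx, Flt3ITD and NPMc_Flt3ITD.

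**Figure D1:**
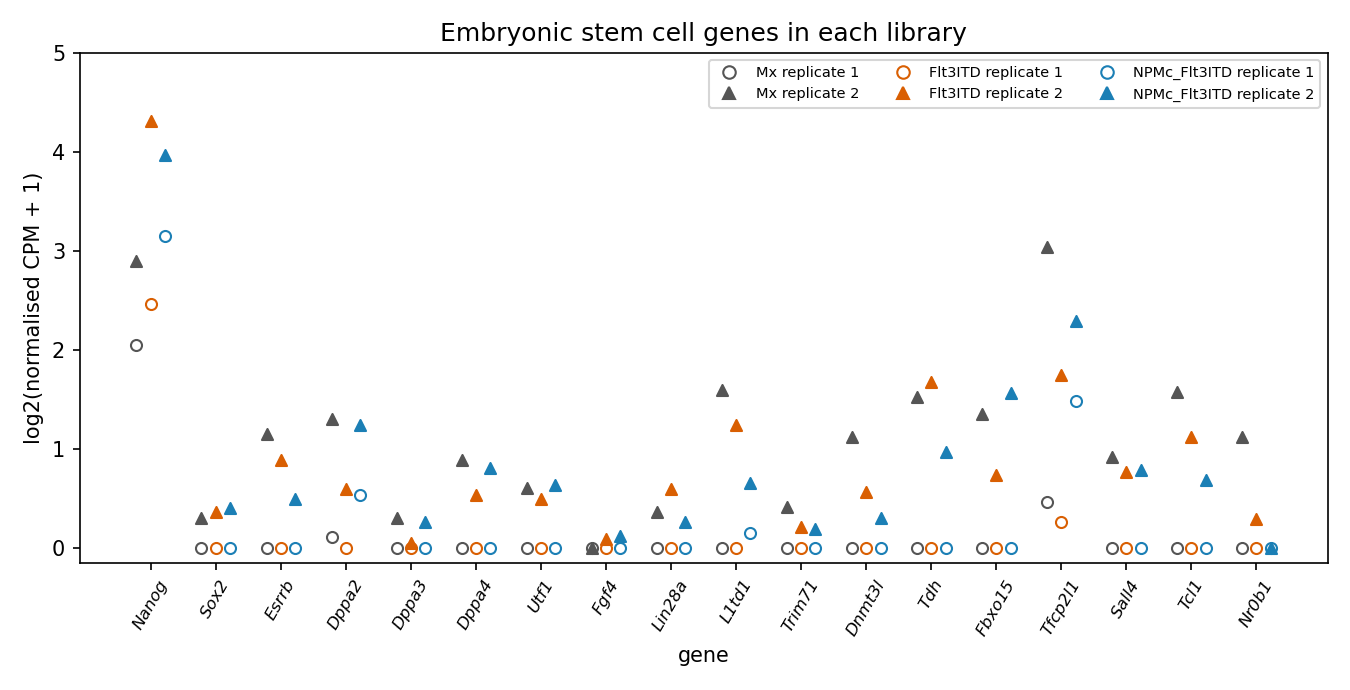
Normalised CPM on the log2(CPM + 1) scale (vertical axis) of 18 genes of embryonic stem cells (horizontal axis) in each of the 6 libraries, with open circles for replicate 1, filled triangles for replicate 2 and colours for the groups. For 16 of the 18 genes the replicate 2 library lay above the replicate 1 library in all 3 groups, the exceptions being Fgf4 and Nr0b1, and Nanog was above 0 in every library.

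Flt3ITD LT-HSC carried more transcripts of erythroid genes than Mx LT-HSC. Of 23 tested erythroid genes 13 rose, none fell and 10 did not pass, with a median log2 fold change of 2.21. Car1, the carbonic anhydrase of red cell precursors, rose from 137 ± 19.6 to 1432 ± 19.7 CPM (log2 fold change 3.38, SE 0.54, adjusted p = 0.0196). Ermap, an erythroid membrane protein gene, rose from 14.3 ± 3.16 to 152 ± 19.8 CPM (adjusted p = 0.00728) and Rhd, a blood group antigen gene, from 4.16 ± 0.157 to 49.4 ± 11.8 CPM (adjusted p = 0.00747). When adjusted over the list alone, 20 erythroid genes rose. The list as a whole passed camera (adjusted p = 2.87e-15), but not when its inter-gene correlation was estimated (adjusted p = 0.161 with an estimated correlation). Alas2 and Slc4a1, genes of late red cell precursors, averaged only 2.14 ± 1.91 and 0.349 ± 0.493 CPM in Flt3ITD. The largest rises over all genes included the list members Mt2, a metallothionein (log2 fold change 3.92), Cldn13, a claudin (3.83), and Sphk1, which makes sphingosine 1-phosphate (3.23). Outside the list Add2, an adducin of the membrane skeleton, rose by 3.15, Atp1b2, a sodium pump subunit, by 3.45, Cited4, a transcriptional cofactor, by 3.29 and the chemokine receptor gene Cx3cr1 by 3.78. The iron exporter gene Slc40a1 rose by 2.08 (adjusted p = 0.0163).

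Genes that mark LT-HSC fell in Flt3ITD. Of 28 tested LT-HSC identity genes 9 fell and none rose, or 13 when adjusted over the list alone, with a median log2 fold change of -0.82. Mecom, a transcription factor needed for stem cell maintenance, fell from 106 ± 5.74 to 26.6 ± 9.64 CPM (SE 0.25 on the log2 scale, adjusted p = 0.00934). Procr, the endothelial protein C receptor used to purify LT-HSC, fell from 86.7 ± 1.24 to 23.4 ± 2.77 CPM, and Esam, an adhesion molecule, from 141 ± 3.27 to 51.4 ± 0.492 CPM. The identity list passed camera with an adjusted p of 3.93e-09 (adjusted p = 0.143 with an estimated correlation). Of 31 quiescence and dormancy genes 8 fell and none rose, or 16 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.27e-08, adjusted p = 0.0707 with an estimated correlation). Among them the cyclin-dependent kinase inhibitor gene Cdkn1a fell from 48.0 ± 3.52 to 16.3 ± 2.55 CPM, and the imprinted growth suppressor gene Ndn fell by 2.88, Clec1a by 2.59 and the nuclear receptor gene Nr4a2 by 1.84 on the log2 scale. Cdkn1c, another inhibitor, was at 4.75 CPM in Mx and 2.01 CPM in Flt3ITD and did not pass (log2 fold change -1.06, SE 0.63, adjusted p = 0.337). In the Hoxa cluster 1 of 8 genes fell, Hoxa10, from 39.0 ± 0.983 to 16.4 ± 1.05 CPM (adjusted p = 0.0374). The count was the same when adjusted over the list alone (camera adjusted p = 0.00492, adjusted p = 0.183 with an estimated correlation). Hoxa9 did not pass (log2 fold change -0.69, adjusted p = 0.137), nor did its partner Meis1 (-0.89, adjusted p = 0.0895). Both passed with replicate number as a block, with adjusted p of 0.0419 and 0.00417.

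Cell cycle genes were higher in Flt3ITD. Of 34 G2/M phase genes 9 rose, or 27 when adjusted over the list alone, with a median log2 fold change of 0.82 (camera adjusted p = 3.16e-14, adjusted p = 0.183 with an estimated correlation). Ube2c, a mitotic ubiquitin-conjugating enzyme, rose from 44.3 ± 7.95 to 112 ± 3.37 CPM and Birc5, or survivin, from 48.1 ± 10.8 to 122 ± 3.28 CPM. Of 34 G1/S and S phase genes 8 rose, or 22 when adjusted over the list alone, with a median of 0.65 (camera adjusted p = 3.19e-13, adjusted p = 0.143 with an estimated correlation). They included Cdc6, which licenses replication origins (33.0 ± 4.26 to 88.2 ± 8.48 CPM), and the ribonucleotide reductase gene Rrm2 (84.4 ± 13.9 to 178 ± 1.06 CPM). The proliferation marker Mki67 was at 122 ± 7.23 and 197 ± 11.5 CPM and did not pass (adjusted p = 0.0644, or 0.0108 with the block). Nor did Cdk6 (log2 fold change 0.55, SE 0.20, adjusted p = 0.146, or 0.0386 with the block). Of 39 ribosome biogenesis genes 5 rose, or 21 when adjusted over the list alone, among them Nhp2 and Gnl3 (camera adjusted p = 2.12e-11, adjusted p = 0.0707 with an estimated correlation). Of 49 oxidative phosphorylation genes 4 rose, or 14 when adjusted over the list alone, among them Sdhb and Atp5g1 (camera adjusted p = 4.02e-12, adjusted p = 0.326 with an estimated correlation). None of 49 cytosolic ribosomal protein genes changed by either count, although the list passed camera upwards (adjusted p = 0.00492, adjusted p = 0.677 with an estimated correlation).

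Genes of several signalling pathways were lower in Flt3ITD. Of 38 TGF-beta pathway genes 8 fell and none rose, or 15 when adjusted over the list alone (camera adjusted p = 3.93e-09, adjusted p = 0.0707 with an estimated correlation). They included the TGF-beta target Klf10 (189 ± 3.11 to 56.3 ± 7.43 CPM), the inhibitor of differentiation gene Id3 (25.9 ± 4.52 to 1.63 ± 0.917 CPM), and the feedback inhibitors Skil (92.4 ± 12.2 to 22.4 ± 2.84 CPM) and Smad7 (37.3 ± 3.10 to 10.4 ± 0.446 CPM). The ligand gene Tgfb1 was at 11.0 ± 3.64 and 11.9 ± 5.36 CPM and did not pass (adjusted p = 0.934). Of 18 ERK feedback and target genes 6 fell, or 9 with 1 rise when adjusted over the list alone (camera adjusted p = 4.33e-06, adjusted p = 0.32 with an estimated correlation). The ERK phosphatase gene Dusp6 fell from 214 ± 32.4 to 57.8 ± 7.51 CPM, its relative Dusp4 from 15.0 ± 4.26 to 0.130 ± 0.0945 CPM, the inhibitor Spry1 from 78.9 ± 36.1 to 15.0 ± 3.61 CPM and cyclin D1, Ccnd1, from 49.8 ± 10.4 to 12.1 ± 2.24 CPM. Of 24 NF-kB and inflammatory genes 7 fell and 1 rose, or 11 and 1 when adjusted over the list alone (camera adjusted p = 4.48e-05, adjusted p = 0.183 with an estimated correlation). Nfkbiz (-2.24) and the cyclooxygenase gene Ptgs2 (-2.56) were among those that fell. Of 24 immediate early and stress genes 4 fell and 1 rose, or 6 and 1 when adjusted over the list alone (median -0.51, camera adjusted p = 0.00669, adjusted p = 0.578 with an estimated correlation). This list did not pass without Mx replicate 1 (median -0.0344, adjusted p = 0.505) or without Flt3ITD replicate 2 (-0.19, adjusted p = 0.269). Nr4a1 of this list was at 1012 and 451 CPM in the Mx libraries and 130 and 44.5 CPM in the Flt3ITD libraries, and higher in replicate 1 in both. Of 25 STAT5 target genes 3 rose and 1 fell, or 3 and 2 when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.734). Socs2, a cytokine signalling suppressor gene that STAT5 induces, rose from 57.7 ± 4.30 to 140 ± 15.4 CPM (adjusted p = 0.0257). Osm, the gene of the cytokine oncostatin M, and Podxl rose by 1.35 and 1.26 on the log2 scale, and the suppressor gene Socs3 fell by 1.85.

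A few myeloid genes rose and several lymphoid genes fell in Flt3ITD. Of 33 granulocyte-monocyte progenitor genes 5 rose by either count, including the granule protease gene Ctsg (14.0 ± 8.61 to 109 ± 56.1 CPM), Cst7, Nkg7 and the mast cell protease gene Cpa3 (15.5 ± 0.0445 to 47.2 ± 6.81 CPM). The list passed camera (median 0.83, adjusted p = 0.000736, adjusted p = 0.463 with an estimated correlation). Without Flt3ITD replicate 2, the library high in S100a8, its median was -0.10 and it did not pass (adjusted p = 0.506). Of 20 multipotent progenitor genes 3 rose and 1 fell, or 5 and 3 when adjusted over the list alone, and this list did not pass (adjusted p = 0.0664). Its member Cd48, a surface marker that LT-HSC lack, rose from 50.4 ± 14.8 to 253 ± 53.3 CPM and Plac8 from 256 ± 60.7 to 808 ± 82.3 CPM. Of 15 mast cell and basophil genes 3 rose by either count, among them the interleukin 33 receptor gene Il1rl1 (2.30). The list did not pass (adjusted p = 0.472), its median of -0.17 lying below 0 while camera pointed upwards. Of 30 lymphoid priming genes 4 fell and 2 rose, or 12 and 2 when adjusted over the list alone (camera adjusted p = 1.57e-05, adjusted p = 0.371 with an estimated correlation). The largest falls over all genes held the B-lineage genes Igll1 (-4.41), Vpreb3 (-4.15) and Ebf1 (-3.48), whose levels in the reference came mostly from 1 library. Igll1 was at 8.51 CPM in Mx replicate 1 and 73.5 CPM in Mx replicate 2, and Vpreb3 at 9.67 and 48.7 CPM. Ebf1 and Rag1 were listed at 0 in both Flt3ITD libraries, where 3 reads equal 0.197 and 0.0951 CPM, against 11.8 ± 8.83 and 3.87 ± 1.12 CPM in Mx. Of 17 mature B and plasma cell genes 3 fell, or 5 when adjusted over the list alone (median -0.67, camera adjusted p = 0.00462, adjusted p = 0.463 with an estimated correlation). Without Mx replicate 2 the median was -0.30 and the list did not pass (adjusted p = 0.0584). Of 23 T and NK cell genes 2 fell, Cd28 and Tcf7, and 1 rose, or 6 and 2 when adjusted over the list alone (median -0.83, camera adjusted p = 0.00223, adjusted p = 0.463 with an estimated correlation). This list did not pass without Mx replicate 2 (median -0.32, adjusted p = 0.0525) or without Flt3ITD replicate 1 (-0.58, adjusted p = 0.0654). Of 27 megakaryocyte and platelet genes 5 fell, or 7 when adjusted over the list alone, led by the platelet adhesion genes Mmrn1 (148 ± 6.61 to 21.0 ± 2.83 CPM) and Selp (127 ± 5.89 to 25.7 ± 4.72 CPM). This list passed camera downwards (adjusted p = 0.00201, adjusted p = 0.503 with an estimated correlation). The remaining largest falls were Rasl11b, a small GTPase gene (-3.54), Sdc4, a syndecan (-3.42), and Fhl1, a LIM domain gene (-3.14).

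Among 12657 tested genes 576 changed in Flt3ITD against Mx (limma, Benjamini-Hochberg adjusted p under 0.05), 268 higher and 308 lower, and 2991 had an unadjusted p under 0.05. All 576 had libraries of the 2 groups that did not overlap, as had 53.8% of all tested genes, where chance gives 33.3%. Camera called 23 of 32 lists, 7 upwards and 16 downwards, and none with an estimated correlation, while fry called 11. Without 1 library or another 9 of the 23 did not pass, namely the granulocyte-monocyte, immediate early, B and plasma cell, T and NK cell, interferon, p53, stromal, glycolysis and cytosolic ribosomal protein lists. Beyond those above, the lists of interferon response genes (adjusted p = 0.0269, not passed with the block at 0.064, and adjusted p = 0.503 with an estimated correlation), p53 targets, stromal and endothelial genes, glycolysis and hypoxia genes, and adhesion and niche genes were lower, the last 4 with adjusted p of 0.0459, 0.0269, 0.0269 and 0.00493 (adjusted p = 0.326, 0.371, 0.214 and 0.183 with an estimated correlation). In these 4 lists 2, 1, 2 and 4 genes fell, or 4, 5, 3 and 6 when adjusted over the list alone, where 1 adhesion gene rose. Of 44 interferon genes 6 fell, among them Ifi44 and Rsad2, or 8 with 2 rises when adjusted over the list alone. Plk2, a polo-like kinase gene of the p53 list, fell from 82.5 ± 5.66 to 12.4 ± 1.88 CPM. The lists of Hoxb cluster genes (adjusted p = 0.297), Hox cofactors (0.109), G1 cyclins and CDK regulators (0.621), mature neutrophil genes (0.725), macrophage and dendritic cell genes (0.277) and unfolded protein response genes (0.472) did not pass. The count rose to 2341 genes with replicate number as a block. It was 265 with edgeR's quasi-likelihood test on recovered reads. The design had named that test for counts, and its use on recovered reads was added after the data were seen. Scaling to library totals gave 28.8% higher among 624 calls against 46.5% among the 576. No gene passed in limma without Mx replicate 1 (2053 at an unadjusted p under 0.05). The count was 35, 4, 253, 312 and 316 without Mx replicate 2, Flt3ITD replicates 1 and 2 and NPMc_Flt3ITD replicates 1 and 2.

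**Figure D2:**
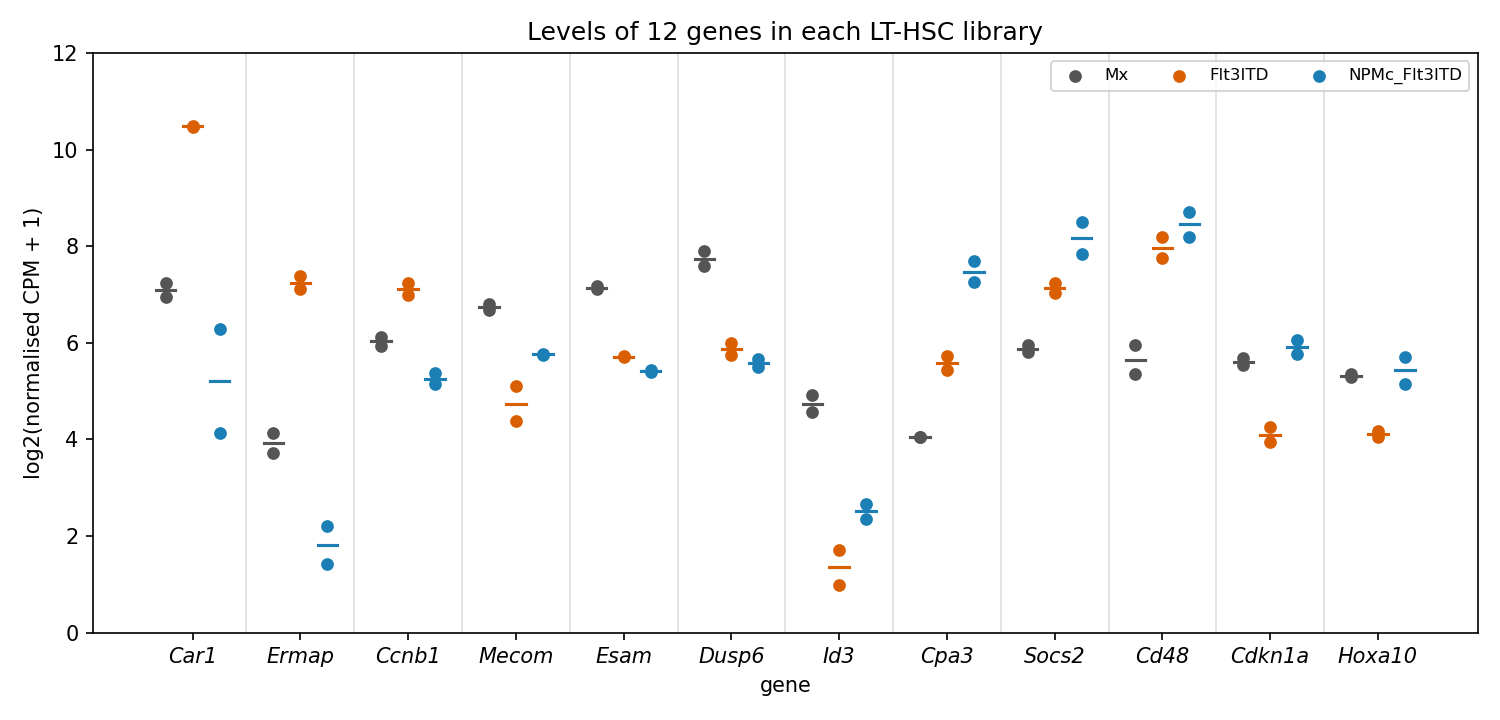
Normalised CPM on the log2(CPM + 1) scale (vertical axis) of 12 genes (horizontal axis) in each of the 6 LT-HSC libraries, with 1 point per library, a bar for the mean of the 2 libraries and colours for the groups. Car1 averaged 137 CPM in Mx, 1432 CPM in Flt3ITD and 46.7 CPM in NPMc_Flt3ITD, while Cpa3 averaged 15.5, 47.2 and 179 CPM.

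LT-HSC with both mutations had more transcripts of myeloid and multipotent progenitor genes than Mx LT-HSC. Of 33 granulocyte-monocyte progenitor genes 4 rose, or 15 when adjusted over the list alone, with a median log2 fold change of 1.24 (camera adjusted p = 2.12e-13, adjusted p = 0.372 with an estimated correlation). Cpa3 rose from 15.5 ± 0.0445 to 179 ± 37.6 CPM (log2 fold change 3.43, SE 0.22, adjusted p = 0.000662) and Ctsg by 3.26 on the log2 scale (SE 0.43, adjusted p = 0.0119), with Nkg7 and Cst7 beside them. Of 20 multipotent progenitor genes 4 rose, or 10 when adjusted over the list alone, with a median of 0.80 (camera adjusted p = 6.09e-11, adjusted p = 0.27 with an estimated correlation). Cd48 rose from 50.4 ± 14.8 to 355 ± 91.3 CPM and Plac8 from 256 ± 60.7 to 879 ± 78.4 CPM, together with Tespa1 and the tetraspanin gene Cd37. Mature neutrophil genes did not pass (median 0.58, camera adjusted p = 0.0545), and S100a8 was at 31.6 and 210 CPM in NPMc_Flt3ITD against 68.2 and 28.1 CPM in Mx. Of 15 mast cell and basophil genes 3 rose, Cpa3, Cyp11a1 and the basophil protease gene Mcpt8, or 4 with 1 fall when adjusted over the list alone (camera adjusted p = 0.00578, adjusted p = 0.372 with an estimated correlation). Of 25 STAT5 target genes 3 rose, or 4 when adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.5 with an estimated correlation). Socs2 rose from 57.7 ± 4.30 to 294 ± 92.1 CPM (adjusted p = 0.00342), Osm from 13.9 ± 2.89 to 125 ± 4.70 CPM and Podxl from 14.6 ± 2.52 to 49.7 ± 1.51 CPM.

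The largest rises in NPMc_Flt3ITD against Mx were in Gzmb, the cytotoxic protease granzyme B (1.09 ± 1.12 to 41.7 ± 17.9 CPM, log2 fold change 4.39), Scin, the actin-severing protein scinderin (4.33), and Apob, the apolipoprotein B gene (3.60). Rab44, a GTPase gene of granulocytic cells (3.56), Akr1c12, an aldo-keto reductase gene (3.49), Alox5, the leukotriene-forming lipoxygenase (3.41), Slc17a8, a glutamate transporter gene (3.32), and the phospholipid transporter gene Atp8b4 (3.23) followed. The receptor gene Pdgfrb rose from 8.17 ± 0.310 to 62.5 ± 4.53 CPM, the surface glycoprotein gene Thy1 from 9.09 ± 1.08 to 39.5 ± 9.04 CPM, the platelet and leukocyte gene Plek by 1.57 and the apoptosis gene Pmaip1 by 2.94 on the log2 scale.

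LT-HSC identity genes were lower in this comparison too. Of 28 tested 4 fell and none rose, or 13 when adjusted over the list alone, with a median log2 fold change of -0.67 (camera adjusted p = 4.04e-08, adjusted p = 0.27 with an estimated correlation). Esam fell from 141 ± 3.27 to 41.6 ± 0.576 CPM, Mllt3, a regulator of stem cell self-renewal, from 161 ± 18.9 to 42.0 ± 2.78 CPM, the angiopoietin receptor gene Tek from 55.8 ± 11.7 to 5.50 ± 2.06 CPM and Procr from 86.7 ± 1.24 to 34.9 ± 10.7 CPM. Mecom was at 53.4 ± 0.515 CPM against 106 ± 5.74 CPM and did not pass (adjusted p = 0.126, or 0.0177 with the block). Of 31 quiescence and dormancy genes 4 fell, or 8 with 1 rise when adjusted over the list alone (camera adjusted p = 0.00458, adjusted p = 0.28 with an estimated correlation). They were Ndn (21.3 ± 7.47 to 0.830 ± 0.0106 CPM), the netrin receptor gene Neo1 (12.9 ± 2.79 to 0.546 ± 0.445 CPM), Clec1a and the imprinted RNA Meg3. Cdkn1c was at 3.31 ± 2.67 CPM against 4.75 ± 2.15 CPM (adjusted p = 0.828). The other largest falls were the imprinted adaptor gene Grb10 (103 ± 11.5 to 8.39 ± 2.23 CPM), Mmrn1 (-3.27), Fhl1 (-3.69), Clca1 (-3.48), Abcg3 (-3.23), Pabpc4l (-3.22), and the B-lineage genes Vpreb3 (-3.94) and Ebf1 (-3.17), the latter pair with the uneven Mx libraries given above. Of 17 mature B and plasma cell genes 1 fell, Ebf1, or 6 when adjusted over the list alone (camera adjusted p = 0.0215, adjusted p = 0.802 with an estimated correlation).

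Of 18 ERK feedback and target genes 3 fell in NPMc_Flt3ITD against Mx, or 7 when adjusted over the list alone (camera adjusted p = 0.000121, adjusted p = 0.5 with an estimated correlation). They were Dusp6 (214 ± 32.4 to 47.0 ± 4.15 CPM), Dusp4 and Ccnd1 (49.8 ± 10.4 to 6.76 ± 0.570 CPM). Of 38 TGF-beta pathway genes 2 fell, Klf10 and Id3, or 8 when adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.27 with an estimated correlation). Tgfb1 did not pass (log2 fold change 0.44, adjusted p = 0.741). Of 44 interferon response genes 2 fell, the guanylate-binding protein gene Gbp6 (29.5 ± 1.81 to 3.47 ± 1.44 CPM) and Ifi44. When adjusted over the list alone 4 fell (camera adjusted p = 1.56e-05, adjusted p = 0.5 with an estimated correlation). Of 23 erythroid genes 2 fell by either count, Ermap (14.3 ± 3.16 to 2.65 ± 1.38 CPM) and Rhd (4.16 ± 0.157 to 0.416 ± 0.0987 CPM), with a median of -0.85 (camera adjusted p = 0.000706, adjusted p = 0.511 with an estimated correlation). No G1/S gene and no G2/M gene changed by either count. The G2/M list passed camera downwards at a median of -0.16 (adjusted p = 0.0355, adjusted p = 0.802 with an estimated correlation), the G1/S list did not pass (adjusted p = 0.867). Mki67 was at 115 ± 20.7 CPM against 122 ± 7.23 CPM (adjusted p = 0.895). Cdk6 did not pass either (log2 fold change 0.76, adjusted p = 0.141, or 0.0218 with the block). The Hoxa list did not pass (adjusted p = 0.722), with 0 genes changed over all genes and 1 higher when adjusted over the list alone. Hoxa9 was at 39.8 ± 5.18 CPM against 30.2 ± 5.15 CPM (adjusted p = 0.611), Hoxa10 at 42.9 ± 11.8 CPM against 39.0 ± 0.983 CPM (adjusted p = 0.914) and Meis1 at 365 ± 143 CPM against 428 ± 69.2 CPM (adjusted p = 0.758). The Hoxb list was lower (camera adjusted p = 0.0238, adjusted p = 0.429 with an estimated correlation), with 0 of 6 genes changed over all genes and 1 when adjusted over the list alone. The lists of cytosolic ribosomal protein genes (camera adjusted p = 7.3e-08) and oxidative phosphorylation genes (0.0238) were higher with no member changed by either count (adjusted p = 0.802 for both with an estimated correlation).

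Among the 12657 genes 148 changed in NPMc_Flt3ITD against Mx, 65 higher and 83 lower, all with libraries that did not overlap, which held for 42.5% of all tested genes. Camera called 15 of 32 lists, 6 upwards and 9 downwards, none with an estimated correlation, and fry called none. Without 1 library or another 7 of the 15 did not pass, namely the Hoxb, oxidative phosphorylation, G2/M, STAT5, B and plasma cell, mast cell and erythroid lists, the last without NPMc_Flt3ITD replicate 2 (median -0.55, adjusted p = 0.0991). The count rose to 689 genes with replicate number as a block, and scaling to library totals gave 32.8% higher among 204 calls against 43.9% among the 148. It fell to 26 and 44 without Mx replicates 1 and 2, and to 42 and 20 without NPMc_Flt3ITD replicates 1 and 2.

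Many of the erythroid and cell cycle genes that rose in Flt3ITD fell when NPMc+ was also present. Of the genes that rose against Mx, 12 of 13 erythroid, 7 of 9 G2/M and 4 of 8 G1/S genes fell. Both comparisons use the same Flt3ITD libraries, so such reversals also arise without any change, and these counts alone do not measure an effect of NPMc+. With 1 Flt3ITD library given to each comparison, in both orders, a split chosen after the data were seen, the erythroid medians were 2.16 with -2.91 and 2.27 with -3.25. Those of G2/M genes were 0.998 with -0.88 and 0.67 with -1.03, and those of G1/S genes 0.70 with -0.64 and 0.54 with -0.76. The comparison of NPMc_Flt3ITD with Flt3ITD asks what NPMc+ adds on the Flt3ITD background. Here 13 of 23 erythroid genes fell and none rose, or 19 when adjusted over the list alone, with a median log2 fold change of -3.22 (camera adjusted p = 8.17e-22, adjusted p = 0.15 with an estimated correlation). Car1 fell from 1432 ± 19.7 to 46.7 ± 42.7 CPM (log2 fold change -5.28, SE 0.54, adjusted p = 0.00438), Ermap from 152 ± 19.8 to 2.65 ± 1.38 CPM (-5.43, SE 0.33, adjusted p = 0.00101) and Rhd from 49.4 ± 11.8 to 0.416 ± 0.0987 CPM. Add2, Atp1b2, Cldn13, Mt2, Sphk1, the erythroid transporter gene Tspo2 and the pseudokinase gene Trib2 made up the rest of the 10 largest falls, with log2 fold changes between -5.45 and -4.46. Slc40a1 fell from 33.8 ± 0.232 to 1.46 ± 0.104 CPM. Of 34 G2/M genes 9 fell, or 28 when adjusted over the list alone (camera adjusted p = 1.14e-21, adjusted p = 0.155 with an estimated correlation). Cyclin B1, Ccnb1, was at 137 ± 16.4 and 37.5 ± 4.27 CPM, Ube2c at 112 ± 3.37 and 37.3 ± 2.34 CPM, and the centromere gene Cenpa at 109 ± 8.16 and 44.6 ± 5.68 CPM in Flt3ITD and NPMc_Flt3ITD. Of 34 G1/S genes 4 fell, or 22 when adjusted over the list alone, namely Rrm2 (178 ± 1.06 to 62.7 ± 5.49 CPM), Fen1, cyclin E1, Ccne1, and Cdc6 (camera adjusted p = 5.44e-16, adjusted p = 0.15 with an estimated correlation). Mki67 was at 197 ± 11.5 and 115 ± 20.7 CPM and did not pass (adjusted p = 0.0762, or 0.00925 with the block).

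**Figure D3:**
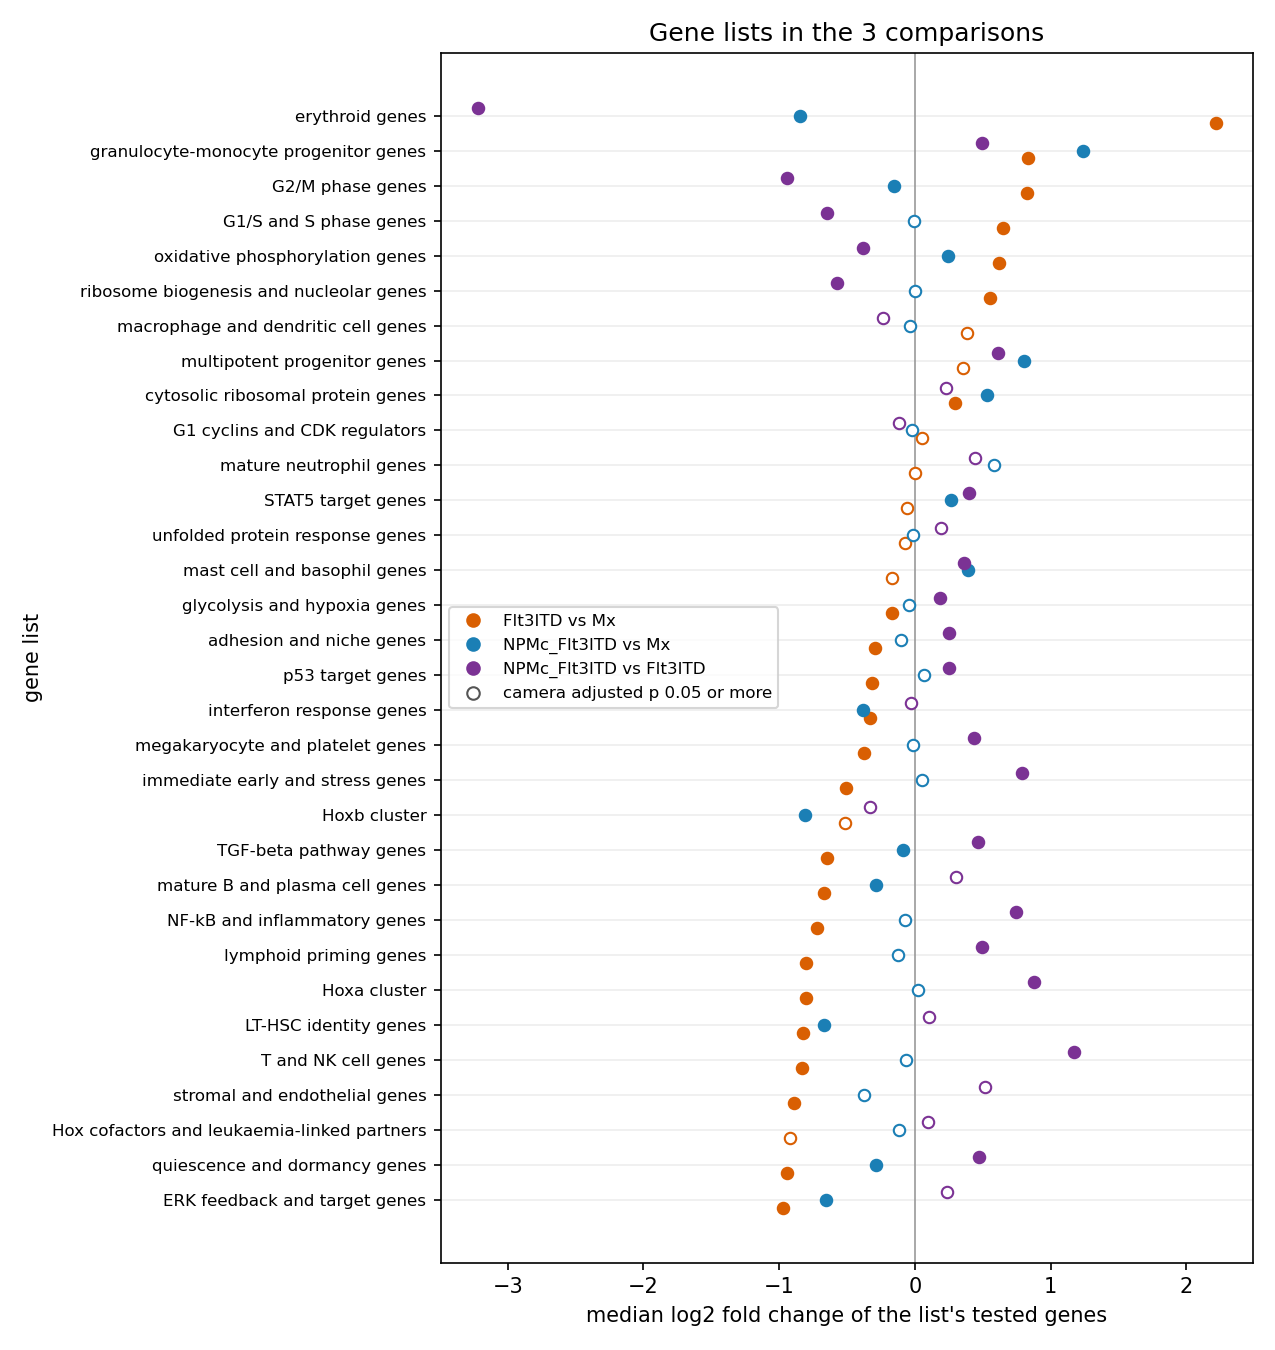
Median log2 fold change of the tested genes (horizontal axis) of each of the 32 gene lists (vertical axis) in the 3 comparisons, in 3 colours, with filled circles where camera with a preset correlation gave an adjusted p under 0.05 and open circles elsewhere. Erythroid genes had the largest spread, with medians of 2.21 in Flt3ITD against Mx, -0.85 in NPMc_Flt3ITD against Mx and -3.22 in NPMc_Flt3ITD against Flt3ITD, and no list passed with an estimated correlation.

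Ribosome biogenesis genes and oxidative phosphorylation genes were also lower in NPMc_Flt3ITD than in Flt3ITD. Both lists were higher in Flt3ITD against Mx, and the shared Flt3ITD libraries favour opposite signs without any change. None of 39 ribosome biogenesis genes passed over all genes and 23 fell when adjusted over the list alone (camera adjusted p = 4.22e-14, adjusted p = 0.133 with an estimated correlation). Nolc1 of this list was at 206 ± 19.1 and 112 ± 22.0 CPM (adjusted p = 0.0614, or 0.00297 with the block). Of 49 oxidative phosphorylation genes 1 fell, Cyc1, the cytochrome c1 gene, or 7 when adjusted over the list alone (camera adjusted p = 1.16e-08, adjusted p = 0.373 with an estimated correlation). The list of cytosolic ribosomal protein genes did not pass (adjusted p = 0.107) but did with the block, upwards (0.000409).

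Quiescence genes were mostly higher in NPMc_Flt3ITD than in Flt3ITD, 27 of 31 by their means. Of these 31 genes 1 rose, Cdkn1a, from 16.3 ± 2.55 to 59.9 ± 8.74 CPM (log2 fold change 1.82, SE 0.22, adjusted p = 0.00861), or 6 with 1 fall, Neo1 (-1.56), when adjusted over the list alone (camera adjusted p = 0.000886, adjusted p = 0.155 with an estimated correlation). Egr1, Nr4a1, Junb, Btg2 and Zfp36 of this list are also in the immediate early list. The quiescence, p53 and Hoxa lists were lower in Flt3ITD against Mx, and the shared Flt3ITD libraries favour opposite signs without any change. No split of the Flt3ITD libraries was made for these lists. Of 28 p53 target genes 2 rose, Cdkn1a and Trp53inp1 (37.5 ± 1.53 to 83.0 ± 3.99 CPM), or 7 with 1 fall when adjusted over the list alone (camera adjusted p = 0.00663, adjusted p = 0.201 with an estimated correlation). Of 8 Hoxa genes 1 rose, Hoxa10, from 16.4 ± 1.05 to 42.9 ± 11.8 CPM, with an adjusted p just inside the threshold (0.04998), or 4 when adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.172 with an estimated correlation). Hoxa9 was at 18.3 ± 2.40 and 39.8 ± 5.18 CPM (adjusted p = 0.0758, or 0.00966 with the block). Meis1 differed by 0.61 on the log2 scale (adjusted p = 0.259, or 0.0294 with the block). The homeobox gene Nkx2-3 rose from 10.2 ± 1.30 to 37.7 ± 8.48 CPM. The LT-HSC identity list did not pass (adjusted p = 0.119), with 1 of 28 genes higher, the RNA-binding protein gene Msi2 (180 ± 32.1 to 347 ± 16.8 CPM), or 3 when adjusted over the list alone. Mecom was at 26.6 ± 9.64 and 53.4 ± 0.515 CPM (adjusted p = 0.0804, or 0.0096 with the block) and the niche signal gene Angpt1 at 318 ± 30.2 and 544 ± 79.9 CPM (adjusted p = 0.0804, or 0.00615 with the block). Cdkn1c (log2 fold change 0.55, adjusted p = 0.692), Cdk6 (0.21, adjusted p = 0.627) and Tgfb1 (0.37, adjusted p = 0.672) did not pass.

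Some of the signalling lists that were lower in Flt3ITD than in Mx were higher in NPMc_Flt3ITD than in Flt3ITD, with few single genes past the test. The shared Flt3ITD libraries favour opposite signs without any change. With 1 Flt3ITD library given to each comparison the medians were -0.67 with 0.49 and -0.71 with 0.45 for TGF-beta genes, -1.01 with 0.49 and -0.54 with 0.97 for NF-kB genes, and -0.19 with 0.98 and -0.86 with 0.32 for immediate early genes. None of 38 TGF-beta genes passed over all genes and 4 rose when adjusted over the list alone (camera adjusted p = 0.000172, adjusted p = 0.15 with an estimated correlation). Of 24 NF-kB genes 1 rose, the chemokine gene Ccl4, or 10 when adjusted over the list alone (camera adjusted p = 2.4e-05, adjusted p = 0.201 with an estimated correlation). Nfkbiz just missed the threshold (1.33, adjusted p = 0.0507, or 0.00204 with the block). None of 24 immediate early genes passed, with 8 rises and 1 fall when adjusted over the list alone (median 0.79, camera adjusted p = 0.00109, adjusted p = 0.555 with an estimated correlation). The list did not pass without Flt3ITD replicate 2 (median 0.32, adjusted p = 0.161) or without NPMc_Flt3ITD replicate 1 (0.32, adjusted p = 0.196). Its member Junb differed between replicates of each group as given above. The ERK list did not pass (adjusted p = 0.191). Of 25 STAT5 targets 1 rose, Osm (38.7 ± 17.5 to 125 ± 4.70 CPM), or 5 when adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.201 with an estimated correlation). Socs2 was at 140 ± 15.4 and 294 ± 92.1 CPM (adjusted p = 0.07, or 0.00473 with the block). The interferon list did not pass (adjusted p = 0.327), with Gbp2 (208 ± 58.6 to 64.0 ± 0.340 CPM) and Gbp6 the 2 of 44 genes that fell, or 9 with 3 rises when adjusted over the list alone.

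Genes of T lymphocytes were among the largest rises in NPMc_Flt3ITD against Flt3ITD. Tcf7, a transcription factor of early T cells, rose from 0.414 ± 0.400 to 19.9 ± 2.74 CPM (log2 fold change 3.91, SE 0.52, adjusted p = 0.0106), the kinase gene Lck from 11.1 ± 0.211 to 44.4 ± 7.51 CPM and Thy1 from 8.25 ± 1.46 to 39.5 ± 9.04 CPM. These were the 3 of 23 T and NK cell genes that rose, or 6 when adjusted over the list alone (camera adjusted p = 2.54e-07, adjusted p = 0.28 with an estimated correlation). The nuclear factor gene Tox rose beside them (6.99 ± 2.17 to 30.6 ± 10.2 CPM). In Mx, Tcf7 was at 8.49 ± 6.38 CPM, Lck at 17.0 ± 5.69 CPM and Thy1 at 9.09 ± 1.08 CPM. The T and NK cell list did not pass in NPMc_Flt3ITD against Mx (median -0.0653, camera adjusted p = 0.158), where 3 of its genes rose. It was lower in Flt3ITD against Mx, and the shared Flt3ITD libraries favour opposite signs without any change. In NPMc_Flt3ITD against Flt3ITD 2 of 30 lymphoid priming genes rose, Tcf7 and Lck, or 7 with 2 falls when adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.495 with an estimated correlation). Further large rises were Hnf4a, a nuclear receptor gene of liver and gut (5.78 ± 3.16 to 65.6 ± 8.69 CPM), Pdgfrb (10.1 ± 0.617 to 62.5 ± 4.53 CPM), Akr1c12, the steroid-forming gene Cyp11a1, the lectin gene Clec2i and Cpa3 (47.2 ± 6.81 to 179 ± 37.6 CPM). Cpa3 was the 1 of 33 granulocyte-monocyte progenitor genes that rose by either count (median 0.49, camera adjusted p = 0.000196, adjusted p = 0.471 with an estimated correlation). Without Flt3ITD replicate 1 the median was -0.0818 and the list did not pass (adjusted p = 0.546). Cpa3 and Cyp11a1 were the 2 of 15 mast cell genes that rose, or 3 with 1 fall when adjusted over the list alone (camera adjusted p = 0.0267, adjusted p = 0.253 with an estimated correlation). None of 20 multipotent progenitor genes passed over all genes, with 7 rises and 1 fall when adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.201 with an estimated correlation). Of the megakaryocyte list Plek rose, of the glycolysis and hypoxia list the aldolase gene Aldoc (15.7 ± 0.609 to 56.1 ± 0.350 CPM), and of the adhesion and niche list Thy1. These 3 lists passed camera with adjusted p of 0.0136, 0.0334 and 0.0497 (adjusted p = 0.599, 0.201 and 0.222 with an estimated correlation). When adjusted over the list alone 1, 2 and 2 of their genes rose.

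Among the 12657 genes 149 changed in NPMc_Flt3ITD against Flt3ITD, 35 higher and 114 lower, all with libraries that did not overlap, which held for 48.2% of all tested genes. Camera called 20 of 32 lists, 15 upwards and 5 downwards, none with an estimated correlation, and fry called 10. Without 1 library or another 8 of the 20 did not pass, namely the granulocyte-monocyte, immediate early, p53, lymphoid priming, megakaryocyte, mast cell, glycolysis and adhesion lists. The count rose to 1513 genes with replicate number as a block and was 77 with edgeR's quasi-likelihood test on recovered reads. It fell to 25 without Flt3ITD replicate 1, and to 54 and 24 without NPMc_Flt3ITD replicates 1 and 2.

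Of the genes changed in the 2 mutant groups against Mx, 77 were shared, 73 in the same direction (20 higher and 53 lower) and 4 in opposite directions. Independent lists of these sizes would share 1.38 higher and 2.02 lower genes. Both comparisons use the same Mx libraries, and in 50 simulations of unchanged groups the same number of top genes shared 50.5 in the same direction and 0.62 in opposite directions on average. These top genes were taken by rank of p whether or not any passed. The simulated overlaps, here and below, are therefore not those expected among called genes and do not show how many shared calls the shared libraries explain. The covariance of log2 fold changes across genes was 0.214 against 0.0780 in those simulations (correlation 0.559 against 0.501, genes not being independent replicates). Of the genes changed by Flt3ITD against Mx, 100 also changed between NPMc_Flt3ITD and Flt3ITD, of which 83 were higher and then lower and 13 lower and then higher. Independent lists would share 2.41 and 0.852, and the simulated groups, which share the Flt3ITD libraries, gave 49.1 in opposite directions (covariance -0.223 against -0.0783, correlation -0.576 against -0.502). NPMc_Flt3ITD against Mx and against Flt3ITD shared 24 genes, all in the same direction. Independent lists would share 0.18 higher and 0.748 lower genes, and the simulated groups gave 23.7 (covariance 0.12 against 0.0772, correlation 0.355 against 0.497). With the replicate block the 3 overlaps were 390, 919 and 228 genes, and the simulated groups hold no replicate effect. With 1 library of the shared group given to each comparison, in both orders, the covariances were 0.149 and 0.147 for the first pair, -0.14 and -0.124 for the second and 0.052 and 0.0509 for the third. Calls were not split in this way, as each part would keep 1 library, so part of any excess in shared genes may come from the shared libraries.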

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

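The tests of late red cell precursors, stem cell share, progenitors in the gate, the mix of male and female animals, the chromosomal region of Hprt and an insertion there were chosen after the results were seen, while those on embryonic stem cell genes and sequencing depth were written before.

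The medians of erythroid genes against Mx had opposite signs in the 2 mutant groups. The median log2 fold change of the 23 erythroid genes was 2.21 in Flt3ITD and -0.85 in NPMc_Flt3ITD. The latter rests on 2 genes that fell, did not pass with an estimated correlation (adjusted p = 0.511) and did not pass without NPMc_Flt3ITD replicate 2 (median -0.55, adjusted p = 0.0991). The test of the difference, NPMc_Flt3ITD against Flt3ITD, gave a median of -3.22 (camera adjusted p = 8.17e-22, adjusted p = 0.15 with an estimated correlation). There were 4 genes that changed against Mx in both mutant groups in opposite directions and also between them, Add2, Ermap, Rhd and Slc40a1. Late red cell precursors or reticulocytes among the Flt3ITD cells are argued against by Alas2 and Slc4a1, abundant in such cells, at 2.14 and 0.349 CPM in Flt3ITD where Car1 reached 1432 CPM. A lower share of LT-HSC with all other lineages rising alike is argued against by the lymphoid priming list. Its median of -0.80 lay 3.02 below the erythroid one. Here 25 of 30 genes were lower, though part of the fall came from B-lineage genes, such as Igll1, high in 1 Mx library. A permutation over genes gave p = 1e-05 (two-sided, the smallest that 100000 permutations can give). This p adds no support, as the medians were known beforehand. The permutation also treats genes as independent, while their estimated correlation was 0.209 in the erythroid and 0.306 in the lymphoid list. Early erythroid progenitors inside the sorted gate and an erythroid programme within Flt3ITD stem cells cannot be told apart, because the median of LT-HSC identity genes (-0.82) would fall under either and bulk values do not separate cells, and an effect of the genotype on either may underlie the difference.

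Embryonic stem cell genes set the replicate 2 libraries apart from the replicate 1 libraries in all 3 groups. Of 18 such genes, in a list written before their values were seen, 16 were higher in replicate 2 in all 3 groups, against 3.85 on average among genes of like level (one-sided permutation p = 0.0001, the smallest the draws can give). Deeper sequencing is argued against by the Mx pair, where replicate 2 was the shallower and 17 of the genes were higher in it and 0 in replicate 1 (exact two-sided sign test p = 1.53e-05). Both p-values count genes that may vary together, and the sign test rests on 1 pair of libraries, so neither measures variation between animals. Some counted values lay near the floor, such as Dppa3 at 0.0317 CPM in Flt3ITD replicate 2. A candidate explanation is a small amount of embryonic stem cell RNA or reads in the 3 replicate 2 libraries. Dppa5a at 22.1, 26.7 and 25.2 CPM is an example chosen after its values were seen. However, 4 of the 18 genes, Nanog among them, were above 0 in a replicate 1 library. Whether the sort would remove such cells cannot be told, as its markers are not given. No biological explanation was tested, as the labels do not say what the replicate numbers share.

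Hprt, a housekeeping gene on the X chromosome, was at 201 ± 1.12 CPM in Mx, 248 ± 19.2 CPM in Flt3ITD and 65.5 ± 6.23 CPM in NPMc_Flt3ITD (n = 2 each), with a log2 fold change of -1.91 against Flt3ITD (SE 0.16, limma adjusted p = 0.00191). A different mix of male and female animals is argued against by the 4 libraries without NPMc+, whose Xist levels, from 37.2 to 1038 CPM, span those of the NPMc_Flt3ITD libraries. The lowest of their Hprt levels was 200.1 CPM and the highest in NPMc_Flt3ITD was 69.9 CPM, apart by more than the largest SD within a group (19.2 CPM). A test on X-linked genes written earlier was dropped, since X inactivation keeps most of them alike in both sexes. A loss over the whole surrounding region as large as the fall of Hprt is argued against by its 6 nearest tested neighbours. Their median of -0.43 lay above the value of Hprt by more than their SD of 0.926. This criterion was reworded after the values were seen. A bound of -0.5 written earlier was also met, though not by more than that SD. The neighbours ranged from -1.27 (Gpc4) to 1.45 (C430049B03Rik) and none passed the limma test, so a smaller or partial loss stays open. A targeted insertion at Hprt in the NPMc line, which the labels do not mention, and an effect of NPMc+ on the gene cannot be told apart at a change of -1.91, because the table gives 1 value per gene and none per exon.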

How the results depend on the processing

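Counts of changed genes depended strongly on the variance model and on single libraries. The edgeR quasi-likelihood fits on recovered reads, fry with the block and the overlaps with the block were chosen after seeing the data. The quasi-likelihood test without the block had been written as the main test for counts, so only its use on recovered reads came later. In the order Flt3ITD against Mx, NPMc_Flt3ITD against Mx and NPMc_Flt3ITD against Flt3ITD, 576, 148 and 149 genes became 1475, 549 and 994 with DESeq2, 1308, 561 and 813 with the edgeR likelihood ratio test, and 2341, 689 and 1513 with replicate number as a block in limma, where all of the 576, 148 and 149 genes passed. The quasi-likelihood test with the block gave 1788, 423 and 1067. Without a filter on low values limma called 0, 27 and 0 of 17997 genes, with 3285, 1912 and 2586 at an unadjusted p under 0.05, and the cause was not tested. For Flt3ITD against Mx, voom gave 296, the 4 libraries compared 337, a pseudocount of 0.1 375 and the quasi-likelihood test 265, and for NPMc_Flt3ITD against Flt3ITD the last gave 77. Leaving out single libraries gave 0 (Mx replicate 1) to 316 genes, 20 (NPMc_Flt3ITD replicate 2) to 169, and 24 (NPMc_Flt3ITD replicate 2) to 108, with fewer samples and 1 group left at a lone library assumed to vary like the others. DESeq2 size factors, the filter at 10 CPM, a pseudocount of 5 and the fold change threshold kept each count within 1.5 times, and library totals did too while moving the median of all genes from 0.01 to -0.10 in Flt3ITD against Mx and from 0.01 to -0.11 in NPMc_Flt3ITD against Mx.

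Shared calls of the 2 mutant groups against Mx went from 77 to 277 with DESeq2, 273 with the likelihood ratio test and 390 with the block. Those of Flt3ITD against Mx and NPMc_Flt3ITD against Flt3ITD went from 100 to 536, 429 and 919, and those of NPMc_Flt3ITD against Mx and against Flt3ITD from 24 to 175, 169 and 228. For gene lists, camera with an estimated correlation called 0, 0 and 0 of 23, 15 and 20, fry 11, 0 and 10, and fry with the block 3 for NPMc_Flt3ITD against Mx and 6 for NPMc_Flt3ITD against Flt3ITD. Camera with the block kept 57 of the 58 list calls, and leaving out single libraries kept between 46 and 54.

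Of the 164 calls of named genes, 164 held with DESeq2 size factors, 161 with library totals and 11 without a filter. Voom and the quasi-likelihood test on recovered reads each kept 128. None changed direction. Between 53 (without Mx replicate 1) and 114 (without Flt3ITD replicate 2) held without a single library. Beyond the changes given with the results, the block changed no other call among the named genes and lists.

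Among called lists the camera direction turned for 3, given below with values that had not passed. Medians of other called lists also changed sign, with camera no longer passing: granulocyte-monocyte progenitor genes in Flt3ITD against Mx (-0.10 without Flt3ITD replicate 2) and in NPMc_Flt3ITD against Flt3ITD (-0.0818 without Flt3ITD replicate 1), and in NPMc_Flt3ITD against Mx STAT5 targets (-0.00813 without Mx replicate 2) and mature B and plasma cell genes (0.0816 without Mx replicate 2 and 0.11 without NPMc_Flt3ITD replicate 1). Under library totals Tgfb1 was at -0.0368 in Flt3ITD against Mx, and Npm1 and Hoxa10 at -0.00868 and -0.0165 in NPMc_Flt3ITD against Mx. Without single libraries Tgfb1 ran from -0.36 to 0.51 in Flt3ITD against Mx and from -0.0643 to 0.81 in NPMc_Flt3ITD against Flt3ITD. In NPMc_Flt3ITD against Mx, Npm1 ran from -0.0608 to 0.30, Hoxa10 from -0.17 to 0.39, Meis1 from -0.69 to 0.13, Cdkn1c from -1.19 to 0.16 and Mki67 from -0.28 to 0.0892, and Cdkn1c ran from -0.19 to 1.28 in NPMc_Flt3ITD against Flt3ITD. Medians of the cytosolic ribosomal protein list ran from -0.13 (without Flt3ITD replicate 2) to 0.79 in Flt3ITD against Mx and from -0.23 to 0.68 in NPMc_Flt3ITD against Flt3ITD, those of oxidative phosphorylation from -0.0355 (without NPMc_Flt3ITD replicate 2) to 0.49 in NPMc_Flt3ITD against Mx, and those of the megakaryocyte list from 0.12 (without NPMc_Flt3ITD replicate 1, where camera turned downwards) to 0.78 in NPMc_Flt3ITD against Flt3ITD. In Flt3ITD against Mx the STAT5 list ran from -0.16 to -0.0598 with camera turning and mature neutrophil genes from -1.49 to 1.40, and in NPMc_Flt3ITD against Mx the G1/S list ran from -0.0774 to 0.0109, at -0.0106 under fry with the block, which turned upwards. The cause was not tested. At these depths 3 reads equal 0.0867 to 0.197 CPM, so lower levels cannot be told from 0.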

Other observations

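Imprinted genes form part of the growth control of LT-HSC, and several were among the falls. Ndn, Grb10 and Meg3 fell in NPMc_Flt3ITD against Mx, which led to the hypothesis that imprinted genes are lower as a set. It was tested on 39 other imprinted genes written before their values were seen, of which 24 could be tested. Their median log2 fold change was -0.13 in NPMc_Flt3ITD against Mx, above the bound of -0.25 named in advance, yet camera gave a shift downwards (p = 0.00594, or 0.0554 with an estimated correlation), with 2 of the 24 lower, Peg12 and Ppp1r9a, and 4 changed when adjusted over the list alone. By the rule named in advance the hypothesis therefore failed in this comparison. The median cleared the bound by less than the SD of the members (0.722), but this demand on the spread was set after the values were seen. Given the camera shift, a drop of the set smaller than the bound stays open. In Flt3ITD against Mx the median was -0.252, past that bound (camera p = 0.00998, or 0.0647 with an estimated correlation), with 4 of the 24 lower, Peg12, Asb4, Phactr2 and Ppp1r9a, and in NPMc_Flt3ITD against Flt3ITD it was 0.09 (p = 0.881) with none changed.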
